A study of Ascaris suum with 62 samples.

How the data were processed

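Chromatin immunoprecipitation with sequencing for CENP-A was run by the authors in 2 libraries for each of 12 stages, 1 with single-end and 1 with paired-end reads, per the labels. The series lists 62 samples, and 24 are used here. The CENP-A input libraries, the CENP-C libraries and the histone mark libraries were not analysed here. Bowtie2 and MACS2 are named in the submitters' processing notes, with versions and settings not given in the sources used here. Per the file headers, each deposited table gives a peak's scaffold, start and end, a coverage column for each of 2 replicates and the mark retained or eliminated. The deposited coverage columns hold whole-number counts of reads per peak: they grew with peak width with log-log slopes of 0.953 to 1.23 over peaks of at least 200 bp, and were not normalized. The headers do not say which column is the single-end library, how peaks were filtered, whether starts count from 0 or 1, or how the input was used. Fold enrichment per peak was not used here. Scaffold names give the assembly as AgBionano_v1.9, and its sequence and annotation were not used here, so coordinates are the authors' and the analyses of gene lists and of peak position against genes were not run. Each stage has 1 peak set for both libraries, so replicate peak calls cannot be compared.

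Reads in peaks were 1005578 to 14901685 per library, and peaks per list 9197 to 21837. Totals of mapped reads were not used here, so depth is known only within peaks. Intervals of read shares cover counting error only. The 2 columns of a stage correlated at 0.344 (testis3) to 0.887 (ovary3) in log reads per kb. Chi-square per degree of freedom between the columns was 1.11 at 7day, 1.20 in L1 and 1.30 at 60hr, close to counting noise but above it, between 2.71 and 8.16 in 8 other lists, and 73.4 in testis3. Chi-square grows with reads as well as with disagreement, so it does not rank the lists by agreement. Nothing says that the libraries of a stage came from separate animals. The stage list was the unit of the permutation, limma and edgeR tests, so their p-values measure the spread between stages. Fisher's exact tests counted windows or scaffolds, and their p-values hold no spread between stages.

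Lengths are end minus start, and no 2 peaks of a list overlapped. Scaffold length was taken as the last peak end over all lists, 284 Mb in all. A block is a run of peaks of 1 mark on a scaffold over all lists, with borders midway between runs. Peaks of opposite mark overlapped in 16 cases. Cover is the percent of a block, span, window or scaffold inside peaks. Per-stage values were compared with two-sided exact permutation tests of the difference of means, with Benjamini-Hochberg adjustment over the 36 comparisons made. Peak number, width and covered length between gonads and embryos with L1 were planned; the comparisons of eliminated with retained peaks and of other stage groups were chosen after the marks were seen. Overlap was the Jaccard index in base pairs, with an exact test over the 15400 partitions of the lists into 4 classes of 3. The planned 100000 resamples gave a permutation p of 7e-05. Each pair was also set against 100 random shifts within scaffolds.

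Windows of 20 kb (at least 5 kb at scaffold ends) with a mean cover of at least 1% were tested with limma (trend and robust moderation), for gonads against the late lists, testis against ovary and embryos timed in hours against the late lists. Scaffolds of at least 20 kb were tested the same way. Testis and ovary lists share the numbers 1 to 3 in the labels, and same-numbered lists deviated together from their tissue means: the correlations over 11219 windows were 0.373, 0.107 and 0.218 for numbers 1, 2 and 3. The pairing was taken from these values, since the labels do not say what the numbers mean, and a fit with the number as a block was added after the data were seen. For gonads against the late lists, where both lists of a number are on the same side, a random block by number was added; limma's duplicateCorrelation gave it -0.0809 in windows and -0.244 in scaffolds, measured about the mean of all 6 gonad lists. A negative value does not make the test stricter, so these fits leave open how far same-numbered lists are independent, and the p-values for gonads against the late lists treat all 6 as independent. The design had been fixed for peak lists with fold enrichment, and the tables turned out to hold read counts. limma on cover stayed the test reported first because the design had fixed it. Cover and reads in peaks both move with how much of each list was called as peak: with lists scaled to the same covered length, windows that rose by cover went from 2257 to 1262 between gonads and late lists and from 481 to 1184 between hours and late lists. edgeR's quasi-likelihood test on reads in peaks per window, both libraries summed, is printed beside it. Intervals of the timing are from 10000 bootstrap draws over scaffolds.

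Regions were named by a rule fixed, like the design and the first set of other settings, before the data were examined: adjacent windows past the threshold whose lists do not overlap were merged, and the 10 with the largest loss and the 10 with the largest gain of covered length were named for gonads against late lists, 5 and 5 for the other comparisons. Where no window passed, the 5 with the largest mean difference each way were named. Also named were the 5 longest scaffolds that passed each way and the widest peak per list; the planned naming of the peak of highest fold was not done.

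The window test was tested on simulated data. The simulation was revised 2 times after low recovery, while the test itself stayed as it was. In the first design noise was drawn across windows, and in the second from each window's own spread, both with smaller changes than in the third; both recovered few of the changed windows or none. The third used larger changes, of 20, 40, 60 and 80 points of cover, only in windows with a mean cover over 5%, and added a set of 3000 changed windows, so its recovery is the most favourable of the 3 designs. With 200 changed windows, gonads against late lists recovered 4%, 44%, 76% and 92% of them over 11377 windows, testis against ovary 0%, 0%, 38% and 54% over 11219 (0% at each size with the number as a block), and hours against late lists 4%, 48%, 86% and 94% over 10928. With 3000 changed windows recovery was 37.3%, 79.2%, 93.2% and 98.4% for gonads against late lists, 16%, 63.5%, 84.5% and 93.6% for testis against ovary (9.07%, 48.3%, 77.6% and 90.3% with the number as a block), and 48.1%, 84.9%, 95.7% and 99.1% for hours against late lists. Of unchanged windows, 4.68% to 5.07% had an unadjusted p under 0.05. The noise of the third design was normal, equal in both groups, independent between lists and not held within the limits of cover. A rate near the threshold was thus built in, and it does not show the rate of false calls in real cover.

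That first set held windows of 10 and 50 kb, lists scaled to the same covered length, no filter, limma without trend or robust moderation, other overlap measures, scaffolds of at least 100 kb, 0hr added to the gonads, testis or ovary lists alone, and each list left out in turn. Settings chosen after seeing the data were rankings by reads per kb (scaled to the reads in peaks) in place of fold enrichment, which gave the upper part of each list by number, 9197 peaks per list or a minimum at the median of all lists; peaks under 200 bp left out; log2 reads and edgeR on reads in peaks; retained windows only; the blocks by gonad number; calls by mark in each setting; the timing with scaled lists and the places of left-out lists; eliminated peaks left out; and each list without its eliminated peak with most reads. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.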

Results

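The series measured where CENP-A, the histone H3 variant that marks centromeric chromatin, sits along the genome of the pig roundworm *Ascaris suum*, a nematode that discards part of its genome from somatic cells during early cleavage (programmed DNA elimination). CENP-A ChIP-seq (sequencing of the DNA that is pulled down with the histone) covered 12 stages. These were testis lists 1 to 3, ovary lists 1 to 3, embryos after 0, 46 and 60 hours and after 5 and 7 days of incubation, and L1 larvae, the first larval stage. The labels do not say what the gonad numbers stand for. Each stage came as 1 list of peaks with the reads of 2 libraries per peak, and each peak carried the authors' mark, retained or eliminated. Reads in peaks ranged from 1005578 to 14901685 per library. The 12 lists held 163819 peaks on 600 scaffolds, of which 4216 were marked eliminated. Peaks marked eliminated lay in 67 blocks on 63 scaffolds, spanning 12.9 Mb or 4.54% of the length that the peaks span. On 23 of these scaffolds every peak was marked eliminated, and 40 scaffolds carried both marks. Below, 5day, 7day and L1 together are called the late lists, and "cover" is the percent of a region's length inside peaks. No stage has replicate lists, so each value per list stands alone, and every SD is between stages.

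The first comparison asked how much of the genome carried CENP-A in gonads, embryos and larvae. Peaks were narrower in gonads, with a mean of the median widths of 1745 ± 210 bp (SD, n = 6) against 2298 ± 407 bp in embryos and L1 (SD, n = 6). Gonad peaks covered 33.1 ± 11.6 Mb and those of embryos and L1 52.4 ± 6.98 Mb. The 3 embryo lists timed in hours had the longest cover of the 12, between 56.6 and 59.7 Mb. Peak numbers overlapped between gonads (12655 ± 3193) and embryos with L1 (14648 ± 4609), from 9197 in testis3 to 21837 at 0hr. In two-sided exact permutation tests over 924 splits of the lists, p was 0.0152 for width, 0.00866 for covered length and 0.413 for number. After Benjamini-Hochberg adjustment over the 36 comparisons of stage values, the exact p for width was 0.0779 and for covered length 0.0714, so neither passed 0.05. A ranking chosen after the data were seen took peaks with at least the median read density of all lists. Among these, gonads had more peaks than embryos and L1, by 5963 on average (exact permutation p = 0.00216). They also had more covered length, by 4.98 Mb (exact permutation p = 0.249). Density relative to the reads in peaks falls by construction as more length is called, so these differences do not show more CENP-A sites in gonads.

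The marks allow DNA that is later discarded to be set against DNA that is kept. In eliminated DNA each late list had less peak cover than any of the other 9 lists. Somatic cells of the late stages should lack this DNA, so low late cover there is largely fixed by the mark, whatever CENP-A does. The same holds for the comparisons of gonads with late lists by mark below. Peaks covered 14.7% of the eliminated spans at 0hr, 6.80% at 46hr, 4.17% at 60hr, 2.39% at 5day, 0.545% at 7day and 0.866% in L1. Retained spans kept their cover over the first 60 hours, at 21.3% at 0hr, 20.5% at 46hr and 21.7% at 60hr, and had 17.9%, 16.5% and 16.6% in the late lists. In gonads the eliminated spans were covered at 4.14% in testis2 to 20.6% in ovary3, and ovary3 was the only one of the 12 lists in which eliminated spans had more cover than retained spans (15.1%).

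The ratio of eliminated to retained cover fell from 0.691 at 0hr to 0.331 at 46hr and 0.192 at 60hr, and was 0.134 at 5day, 0.033 at 7day and 0.052 in L1. Of the 67 eliminated blocks, 58 had less cover at 60hr than at 0hr and 0 had more. At 46hr 55 blocks had less cover than at 0hr and 5 had more. Peaks marked retained numbered 20968 at 0hr, 14802 at 60hr and 11713 at 7day. Those marked eliminated numbered 869, 262 and 33 at the same stages. They made up 3.22% ± 1.01 of peaks in gonads (SD, n = 6) and 0.546% ± 0.405 in the late lists (SD, n = 3), and their share of the reads in peaks was 7.30% ± 3.05 against 0.553% ± 0.538. On the log2 scale the cover ratio was -0.71 ± 0.80 in gonads and -4.03 ± 1.03 in the late lists. For these 3 quantities every gonad list lay above every late list, and the two-sided exact permutation p was 0.0119, the smallest that 84 splits can give. None passed adjustment over the 36 comparisons (adjusted p = 0.0714 for each, exact tests), and blocks of 1 list are not replicates.

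**Figure D1:**
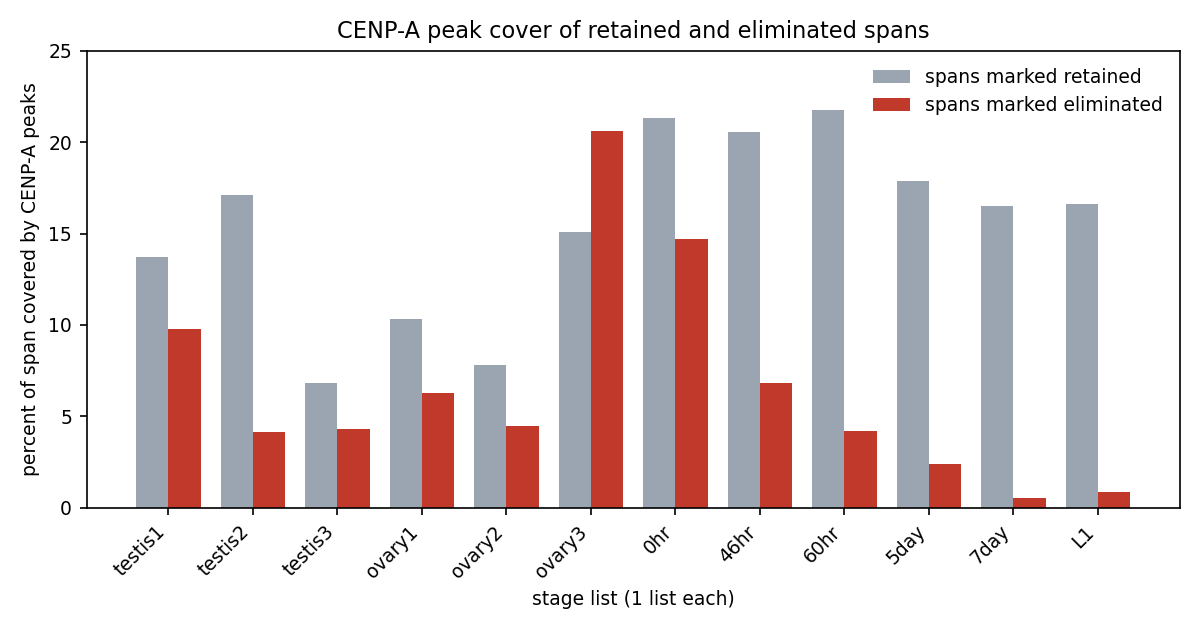
Percent of the spans marked retained (grey bars) and eliminated (red bars) that CENP-A peaks covered, for each of the 12 stage lists. Cover of eliminated spans went from 14.7% at 0hr to 0.545% at 7day, while retained spans stayed between 16.5% and 21.7% from 0hr to L1.

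Single blocks followed the sum to different degrees; those named here were picked by length or by their values after these were seen. The longest, 1583 kb on scaffold 35 (peaks from 89994 to 1634608), had 5.58% ± 5.82 cover in gonads (SD, n = 6), 15.0% at 0hr, 6.17% at 60hr and 0.959% ± 0.999 in the late lists (SD, n = 3). The 843 kb block on scaffold 10 (2674262 to 3514706) had 17.4% at 0hr and 3.27% at 60hr, and none of the 3 late lists had a peak there. Scaffold 204, marked eliminated along its 207 kb, kept 26.9% at 46hr and 19.4% at 60hr against 28.4% at 0hr, and held no late peak. The block of 112 kb on scaffold 236 (4884 to 107165) did not empty: its cover was 11.4% at 60hr and 13.8% ± 1.52 in the late lists. A 133 kb block on scaffold 174 (39056 to 165737) had 25.3% ± 12.6 in gonads, 3.92% at 0hr, 0 at 46hr and 1.30% at 60hr. It then had 33.6% at 5day, 10.0% at 7day and 20.5% in L1. The block was not uniform: from 40001 to 100000 cover was 42.2% ± 12.1 in gonads and 4.48% at 5day, 0% at 7day and 0% in L1. Most of its late cover thus lay in the rest of the block.

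**Figure D2:**
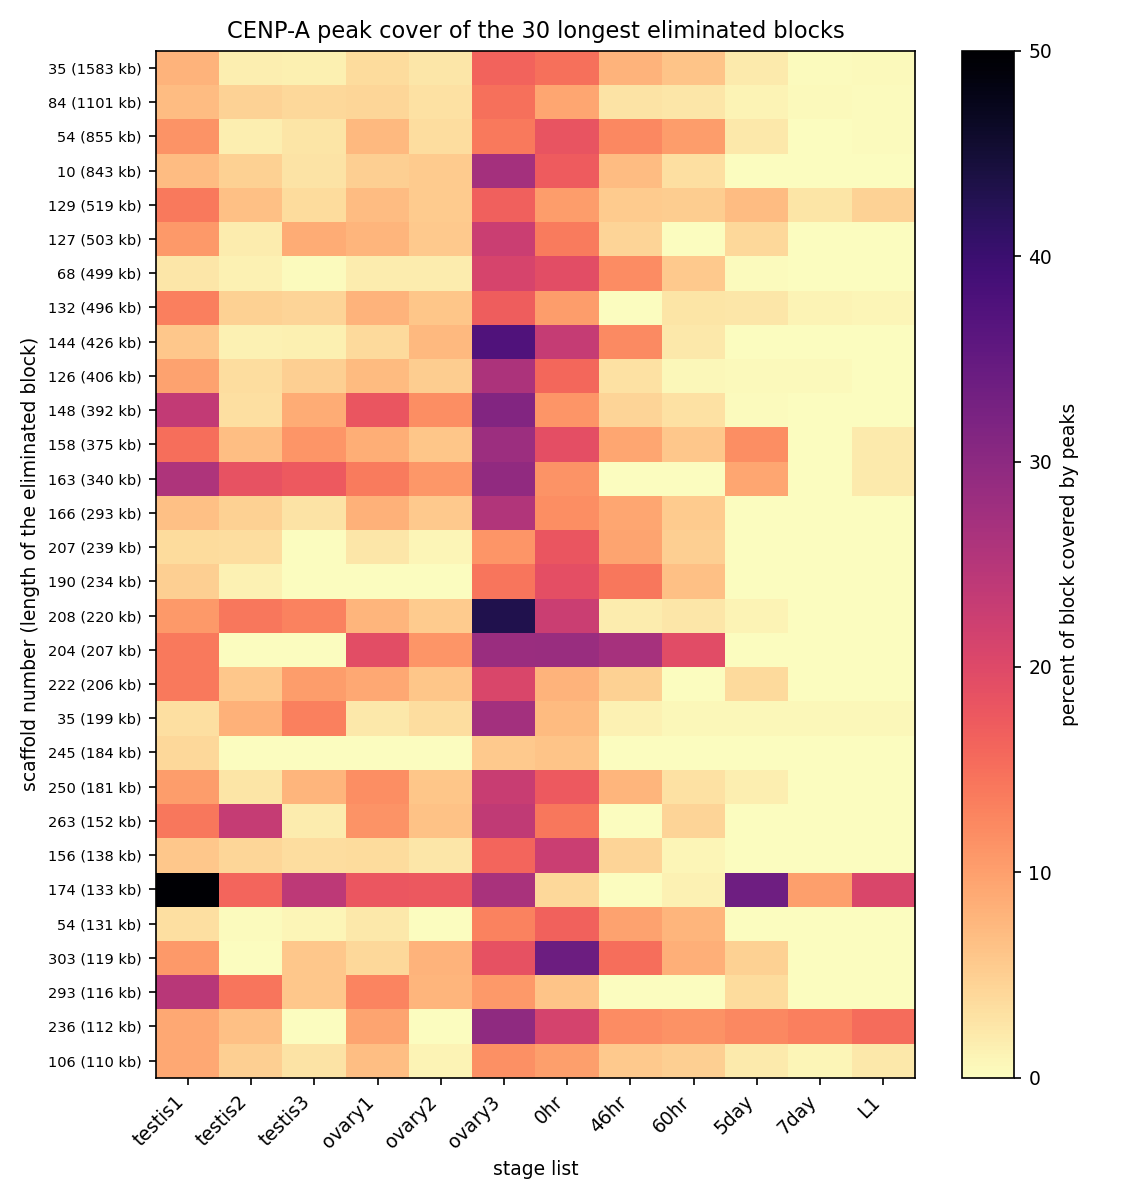
Percent of each of the 30 longest eliminated blocks (rows, with scaffold number and length) covered by CENP-A peaks in each of the 12 stage lists (columns); darker colours mark more cover. Most rows pale from 0hr to 60hr and are near 0 in the late lists. There scaffold 236 has 13.8% ± 1.52 and scaffold 174, at 0% at 46hr, has 21.4% ± 11.8 (SD, n = 3).

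The next comparison asked whether stages of 1 class share their CENP-A sites. The late lists shared the most of their sites, with Jaccard indices (shared length over joint length) of 0.648 to 0.678. Embryos timed in hours shared 0.395 to 0.595, and sites at 60hr overlapped 5day (0.534) more than 0hr (0.395). Gonad lists shared less: the mean was 0.273 among testis lists, 0.271 among ovary lists and 0.232 between testis and ovary. The index cannot exceed the ratio of the 2 covered lengths. These lengths differed more among gonad lists (19.0 to 47.0 Mb) than among late lists (44.8 to 48.8 Mb), which by itself lowers the index. The highest overlap of a testis with an ovary list was 0.422, for testis1 and ovary1, above each of the testis pairs (0.227 to 0.326). The mean of ovary lists with embryos timed in hours, 0.273, was no lower than that among ovary lists. Ovary3 overlapped 0hr (0.425) more than it overlapped ovary1 (0.218) or ovary2 (0.298). The mean was 0.423 within the 4 classes together and 0.250 between them, and the exact permutation p of the difference was 6.49e-05, the smallest that 15400 partitions can give. Each of the 66 pairs lay above its 100 random shifts within scaffolds, by 1.89 to 6.65 times their mean.

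**Figure D3:**
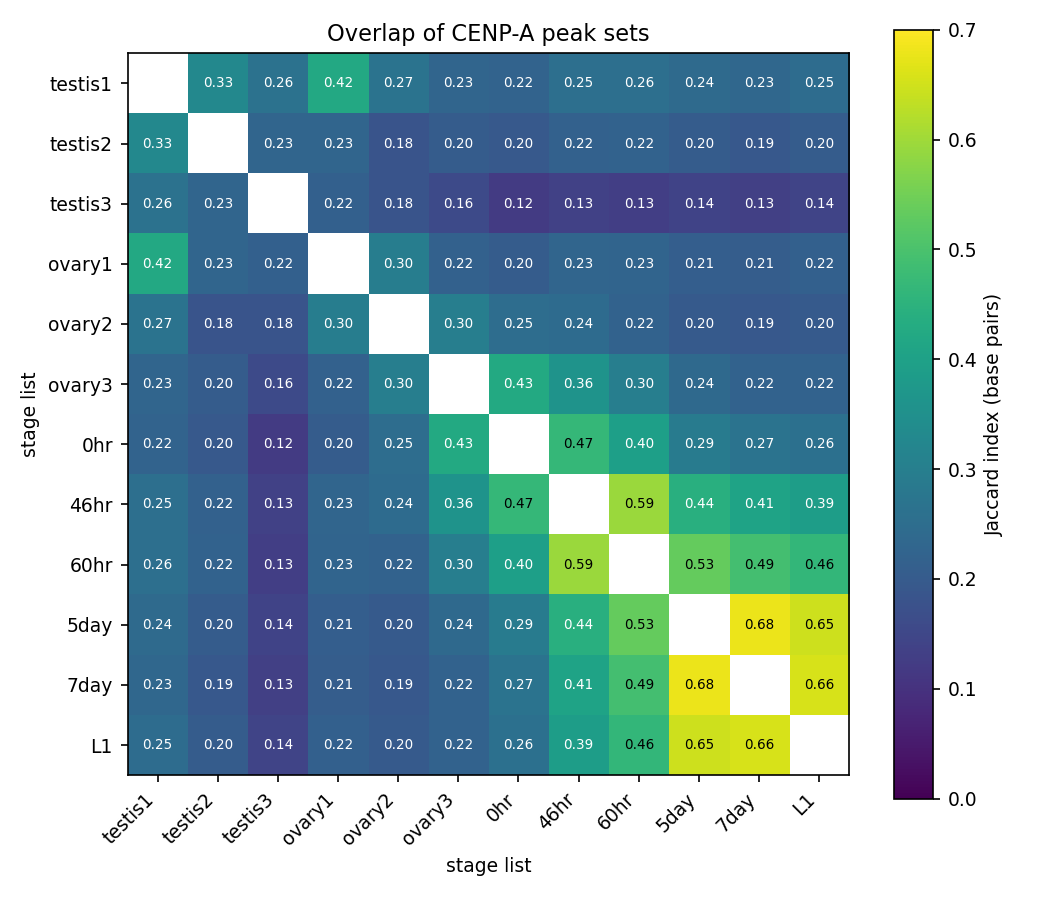
Jaccard index, in base pairs, of each pair of the 12 CENP-A peak sets; the diagonal is left blank. The late lists form the brightest group (0.648 to 0.678), and testis3 has the lowest values, down to 0.122 with 0hr. The index is bounded by the ratio of covered lengths, and testis3 is the shortest list (19.0 Mb). Of its length 45.1% lay in 0hr peaks, against 37.2% for testis2.

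Between gonads and the late lists, CENP-A cover changed in 2552 of 11377 windows of 20 kb (limma, adjusted p under 0.05). It rose in 2257 windows, from a median of 7.75% to 50.4%, and fell in 295 windows, from a median of 39.0% to 0%. The gains lay in retained DNA: 2251 of 10925 retained windows (20.6%) rose, against 6 of 452 eliminated windows (1.33%, Fisher's exact p = 2.71e-35). DNA discarded from somatic cells can hardly gain late peaks, so the direction of the comparisons by mark was largely fixed in advance. They do not show how CENP-A itself changed there. Losses were more frequent in eliminated windows, 26 of 452 (5.75%) against 269 of 10925 retained ones (2.46%; Fisher's exact p = 0.000193), although most lost windows were retained DNA. With 1 late list left out, fewer losses were called in both kinds of DNA, and their share stayed higher in eliminated windows. Without 5day it was 6 of 457 (1.31%) against 0.601% of retained windows (Fisher's exact p = 0.0675). Without 7day it was 5 of 459 (1.09%) against 0.519% (Fisher's exact p = 0.103). Without L1 it was 10 of 459 (2.18%) against 0.694% (Fisher's exact p = 0.00230). Neighbouring windows are not independent, so all Fisher values are too small. Of all tested windows 25.7% had gonad and late lists that did not overlap, against 2.38% for independent lists placed in the groups at random. These lists do not meet that condition: same-numbered gonad lists deviated together, and gonad lists had less covered length in all (33.1 against 46.3 Mb).

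The balance of gains and losses depended on what was counted. Gains were 88.4% of calls by cover, but 43.3% with log2 reads in peaks (657 rose, 859 fell) and 31.2% in edgeR's quasi-likelihood test of those reads (239 rose, 526 fell). Among eliminated windows all 3 measures called mostly losses, the direction that the mark itself largely fixes. By cover 26 fell and 6 rose, and with log2 reads 91 fell and 2 rose. In edgeR, whose read filter kept 273 of the 452, 61 fell and 0 rose. The count of lost windows also fell to 72 without 5day, 62 without 7day and 86 without L1.

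Of the 10 regions with the largest loss of covered length, 9 were retained DNA. The first of them by covered length lay on scaffold 333, with 53.7% ± 11.2 in gonads (SD, n = 6) against 2.36% ± 4.08 in the late lists (SD, n = 3) over its first 80 kb (1 to 80000), with no peak there at 0hr, 46hr or 60hr. Scaffold 40 fell from 43.5% ± 7.43 to 0% between 20001 and 100000, and had 19.1% at 0hr and 2.73% at 46hr. The region marked eliminated was on scaffold 174 from 40001 to 100000, with 42.2% ± 12.1 in gonads and 1.49% ± 2.59 in the late lists. It is part of the block on scaffold 174 described above, whose other part kept late cover. The other 7, of 40 to 60 kb, lay on scaffolds 29, 25, 156, 3, 110, 57 and 42, and went from gonad means of 31.5% to 56.0% to late means of 0% to 9.40%. On scaffold 57 (1540001 to 1580000) cover was still 36.1% at 60hr and then 0% in all 3 late lists.

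The largest gain of covered length was on scaffold 45 from 1320001 to 1420000, where cover rose from 14.6% ± 7.27 in gonads (SD, n = 6) to 68.1% ± 2.81 in the late lists (SD, n = 3). Scaffold 60 held 3 of the 10 largest gains of covered length. At 160001 to 260000 it had 6.68% ± 8.87 in gonads, 84.8% at 60hr and 55.2% ± 5.13 in the late lists; at 620001 to 700000 gonad lists had 1.64% to 29.2% (mean 13.4%) and the late lists 72.9% ± 8.27; and at 1300001 to 1360000 it had 3.38% ± 3.84 and 64.7% ± 9.57. The other 6, on scaffolds 63, 38, 6, 9, 75 and 25, had gonad means of 2.49% to 15.0% and late means of 51.2% to 72.9%. The highest adjusted p of any window in the 20 named regions was 0.0468 (limma). What genes lie in these regions is not analysed here.

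The windows were chosen by their difference between gonad and late lists, so a list that took no part in the choice can lie part of the way between them with no change over time. A gonad list left out lay -14.7% to 28.1% of the way from the other gonad lists to the late lists in gained windows and -27.2% to 46.3% in lost windows, and a late list 89.2% to 103% and 95.0% to 101%. The 3 lists timed in hours also have the longest cover. Windows that gained cover had 11.2% in gonads, 30.2% at 0hr, 39.7% at 46hr, 49.0% at 60hr and 51.4% in the late lists. The 60hr value lay 93.9% of the way from gonad to late (bootstrap interval over scaffolds 90.8 to 96.8). Windows that lost cover went from 40.7% through 32.7%, 22.3% and 17.2% to 3.37%, and were 63.0% of the way at 60hr (54.7 to 70.8). Among these the 26 eliminated windows were 86.2% of the way at 46hr (76.3 to 94.4) and the 269 retained ones 45.7% (37.3 to 54.3). With each list scaled to the same covered length, the 26 eliminated and 264 retained windows then called were at 90.8% (83.4 to 96.3) and 69.2% (64.7 to 73.9). When left out, testis2 lay at 45.3% in eliminated and -23.9% in retained lost windows. Ovary3 lay at -53.1% and 15.3%, and the other gonad lists differed less by mark. A gap by mark as wide as that at 46hr can thus arise in 1 list with no change over time. After scaling, 60hr was 65.0% of the way in gained and 80.6% in lost windows, so which of them lay nearer to the late lists depended on the scaling. At 0hr gained windows were 47.2% of the way by cover in all peaks, and 30.0% in the upper part of each list by read density and 27.3% after scaling. Each time is 1 list, and intervals cover the spread between scaffolds only.

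**Figure D4:**
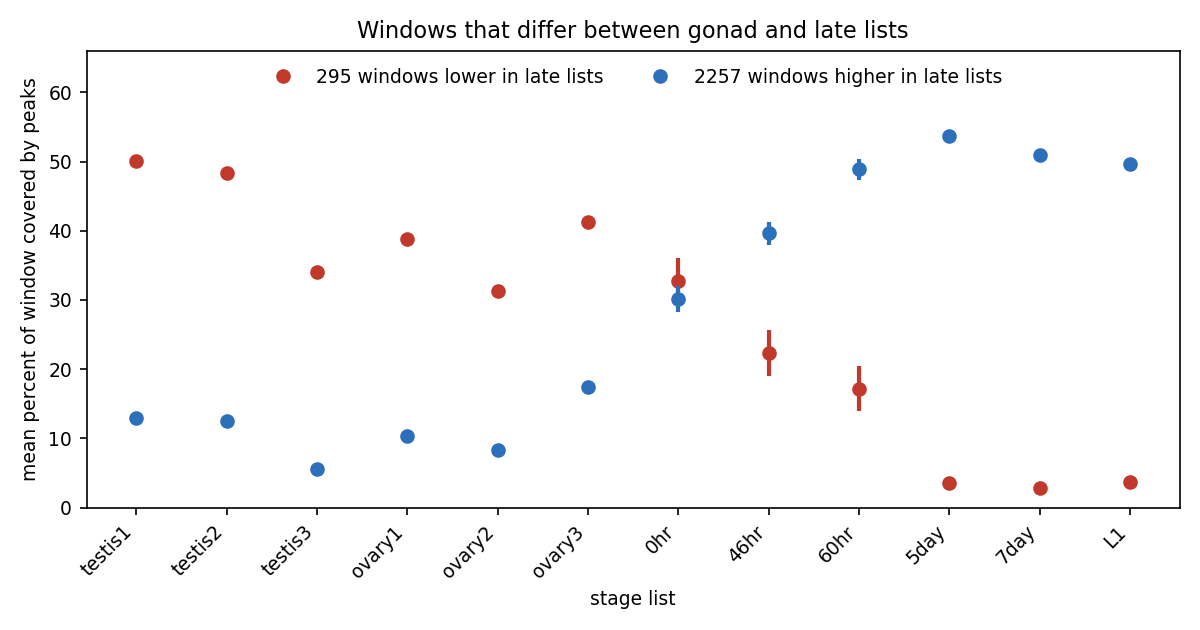
Mean percent of window covered by CENP-A peaks in the 295 windows lower (red) and the 2257 windows higher (blue) in the late lists than in gonads, for each of the 12 lists. Vertical bars at 0hr, 46hr and 60hr are 95% bootstrap intervals over scaffolds; in windows that fell, 0hr (32.7%) lies within the range of the gonad lists (31.2% to 50.1%), and 46hr and 60hr lie between gonads and late lists.

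Whole scaffolds were tested as well, since eliminated DNA comes in long blocks. Cover fell on 10 of 456 scaffolds and rose on 73 (limma, adjusted p under 0.05). Mean cover of all retained spans was 11.8% in gonads and 17.0% in the late lists. No fit with lists scaled to the same covered length was run for scaffolds. How many of the rises only follow that longer cover was not tested. Of the 10 that fell, scaffold 163 was marked eliminated along its whole length and scaffold 293 along most of it; by mark this was 2 of 26 eliminated and 8 of 430 retained scaffolds (Fisher's exact p = 0.106). Scaffold 163 (340 kb) fell from 19.3% ± 7.08 (SD, n = 6) to 3.74% ± 4.87 (SD, n = 3). The other 4 of the 5 longest were retained: scaffold 160 fell from 20.2% ± 3.00 to 9.25% ± 1.73, scaffold 187 from 14.4% ± 5.16 to 1.07% ± 1.86, scaffold 185 from 16.3% ± 5.77 to 4.44% ± 4.02 and scaffold 241 from 21.1% ± 5.23 to 7.85% ± 4.25. These falls were not steady: at 0hr, 46hr and 60hr scaffolds 185 and 241 had no peak and scaffold 160 had 0%, 1.81% and 2.30%, all below their late means. Scaffold 187 had 0%, 1.83% and 0% there, and scaffold 163 had 11.2%, 0% and 0%. The 5 longest that rose, scaffolds 1, 2, 6, 38 and 52, had gonad means of 6.65% to 8.23% and late means of 15.8% to 19.7%. Scaffolds 1, 2, 6 and 38 had 29.1% to 31.6% at 0hr and 24.1% to 27.9% at 46hr and 60hr, above their late means, and scaffold 52 had 15.5%, 15.8% and 18.0%. Adjusted p for these 10 lay between 0.0146 and 0.0488 (limma). Without 5day, 7day or L1 the scaffolds that fell numbered 3, 2 and 2, of which 1, 0 and 0 were eliminated, and those that rose numbered 38, 43 and 39.

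Between testis and ovary lists 0 of 11219 windows passed by limma at an adjusted p under 0.05. Under that threshold without adjustment there were 681 windows. Lists did not overlap in 12.1% of windows, against 10% for independent lists placed in the groups at random. edgeR on the reads in peaks also called 0, with 507 under an unadjusted 0.05, and the log2 reads called 7 lower and 5 higher in ovary. With the gonad number as a block, limma called 0 lower and 1 higher, with 657 under an unadjusted 0.05. Among the windows with the widest gaps of the mean, none of which passed, were scaffold 43, 1280001 to 1300000, with 74.1% ± 23.7 in testis and 8.33% ± 14.4 in ovary (SD, n = 3 each), and scaffold 69, 1300001 to 1308409, with no peak in testis and 79.1% ± 22.5 in ovary. The others lower in ovary lay on scaffolds 17, 125, 4 and 21, and the others higher on scaffolds 351, 30 (2 windows) and 148; of these 10 windows only that on scaffold 148 was marked eliminated. The windows on scaffolds 351, 30 and 69 that were higher in ovary had cover of 90.4% or more at 0hr, 46hr and 60hr, and that on scaffold 148 had 4.92%, 6.82% and 0%. In simulated data this test recovered none of the 20- and 40-point changes where 200 windows changed, and 16% and 63.5% of them where 3000 did, so such differences in few windows were not detectable.

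Between embryos timed in hours and the late lists, cover changed in 1842 of 10928 windows (limma, adjusted p under 0.05). It fell in 1361 windows, from a median of 41.3% to 3.15%, and rose in 481, from 12.6% to 52.9%. The share of windows that fell was 13.0% in eliminated DNA (56 of 432) and 12.4% in retained DNA (1305 of 10496), by cover (Fisher's exact p = 0.711). That comparison depended on the measure and the lists. With log2 reads 118 of 432 eliminated windows fell (27.3%) against 15.5% of retained ones (Fisher's exact p = 1.01e-09). edgeR also called 118, but its read filter kept only 161 of the eliminated windows and 8278 of the retained ones, and windows with few late reads pass it by their reads in the lists timed in hours, so its shares are not compared. By cover without 60hr it was 124 of 447 (27.7%) against 18.7% (Fisher's exact p = 6.56e-06). With lists scaled to the same covered length it was 61 of 400 (15.3%) against 11.1% (Fisher's exact p = 0.0122). With 10 kb windows it was 10.8% against 9.56% (Fisher's exact p = 0.294). Without trend or robust moderation the eliminated share was the lower one (12.7% against 14.0%, Fisher's exact p = 0.479), and in the other settings by cover the higher one. Late cover in eliminated DNA is low by the mark, so a higher share of falls there does not show how CENP-A changed. Rises were rarer in eliminated DNA by cover, which the mark largely fixes here too (6 of 432 against 475 of 10496, Fisher's exact p = 0.000697). The largest fall of covered length was on scaffold 105 from 640001 to 720000, from 62.9% ± 3.96 to 1.26% ± 2.18 (SD, n = 3 each). Others were on scaffolds 77, 72, 41 and 14, from 51.4% to 62.8% down to 0% to 26.5%. The largest rise of covered length was on scaffold 9 from 3720001 to 3820000, from 6.99% ± 1.16 to 54.4% ± 4.72, and others were on scaffolds 71, 125, 23 and 58, from 3.85% to 14.3% up to 48.8% to 76.0%. All 10 regions are retained DNA. Rises were 26.1% of calls, 49.9% once each list was scaled to the same covered length (1188 fell, 1184 rose) and 65.3% with 9197 peaks per list (271 fell, 511 rose). Without 46hr, 5day, 7day or L1 the falls numbered 435, 537, 284 and 336 and the rises 117, 207, 154 and 152; without 60hr they were 2113 and 764.

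The widest peak of each list was retained DNA in 11 of 12 lists. The exception was ovary3, with a peak of 35215 bp on scaffold 158 (83400 to 118615). The widest of all lay on scaffold 37 at 60hr, 48588 bp from 300923 to 349511. The widest peaks of 5day and 7day lay at the same place on scaffold 4, 5329064 to 5374584 and 5328106 to 5364971. Those of the other lists were 46891 bp in testis2 (scaffold 88), 41508 bp in L1 (scaffold 86), 35389 bp in testis1 (scaffold 51), 34878 bp at 46hr (scaffold 41), 31564 bp at 0hr (scaffold 52), 26418 bp in ovary1 (scaffold 34), 26328 bp in testis3 (scaffold 145) and 24240 bp in ovary2 (scaffold 9).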

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

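In this part the test of read density in peaks called at both times was fixed before its result was seen, and the tests of cover and of single blocks were chosen after. A list stood out where its gap to the nearest other list, divided by the range of its group, passed Dixon's 95% critical value for 6 lists. Of 20 groups tested 6 did so, and chance alone gives about 1.

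Ovary3 covered 20.6% of the eliminated spans, and the next gonad list 9.79%. At 0hr 13.3% of the reads in peaks were in eliminated peaks, against 4.97% in the next list of the embryos and L1. One peak marked eliminated, on scaffold 84 from 59593 to 61403, held 5.24% and 3.71% of the 0hr reads in the 2 libraries; without each list's leading eliminated peak the 0hr share was 9.28% and the 46hr share 1.97%. The 2 libraries of testis3 correlated at 0.344, against 0.722 for the next gonad list, and their chi-square per degree of freedom was 73.4, against 8.13. Those of 46hr correlated at 0.786, and the chi-square per degree of freedom of 5day was 8.16, against 3.59 in the next list. That value grows with reads as well as with disagreement, and 5day held the library with most reads in peaks (14901685). By correlation the libraries of 5day (0.879) were like those of 7day (0.872) and L1 (0.886), so the flag may follow depth.

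Eliminated spans lost cover from 0hr to 60hr, and the ratio of eliminated to retained cover at 60hr was 0.278 of that at 0hr (bootstrap interval 0.202 to 0.349). The interval does not cover the choice of peaks: under each ranking by read density the value lay below it, as given further on. Less cover called everywhere would leave that ratio near 1, and retained cover at 60hr was 1.02 of that at 0hr. Retained peaks did fall in number, from 20968 at 0hr to 14802 at 60hr, while the median width of all peaks rose from 1831 to 2265 bp. The level retained cover thus came from fewer and wider peaks. The fall was not due to a few blocks either: of the blocks that differed, 58 had less cover at 60hr and 0 had more. The median fold change of read density in the 191 eliminated peaks called at both times was 0.869 times that in 12061 retained ones (bootstrap interval 0.826 to 0.889), but with 869 eliminated peaks at 0hr and 262 at 60hr this leaves out those that lost most signal, and it does not decide between causes. Loss of CENP-A from this DNA and loss of the DNA itself in part of the cells may each give these values, and they cannot be told apart without input reads, which were not used here.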

How the results depend on the processing

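All rankings by read density, the tests on reads and the comparisons by mark were chosen after the data were seen. Over 277 alternatives of the compared results, 204 kept direction and side of the threshold (for counts, stayed within 1.5 times), 30 were weaker, 21 stronger, 20 moved and 2 reversed; of 560 for named regions and scaffolds, 519 stayed within 1 SD, 41 moved and 0 reversed. The cause was not tested except where given. The regions and scaffolds were named from these same lists for large or passing differences. The lack of reversals among them was thus largely fixed by that choice and is no support for them. Rankings by fold enrichment were not run as planned, nor were the gene alternatives; merging overlapping peaks changed nothing, since none overlapped. Reads in peaks (1005578 to 14901685 per library) limit the read tests, and input depth is unknown.

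With read density of at least the median of all lists, gonads minus embryos and L1 reversed from -1992.5 to 5963 peaks and from -19.4 to 4.98 Mb; by construction, density relative to the reads in peaks falls as more length is called. The ratio of eliminated to retained cover over that at 0hr was then 0.173 at 46hr (0.480 with all peaks) and 0.0581 at 60hr (0.278); at 60hr it was 0.194 in the upper part of each list and 0.191 with equal numbers of peaks.

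From gonads to late lists, 295 windows fell and 2257 rose. With 10 kb windows 448 fell and 3573 rose, and with 50 kb windows 144 and 1139, as their number differs. Falls were 193 in the upper part of each list, 195 with 0hr added to the gonads, 561 with testis lists alone and 481 with ovary lists alone. With log2 reads 859 fell and 657 rose, with edgeR 526 and 239, and 1262 rose with lists scaled to the same covered length. With 1 list left out, falls ranged from 62 to 387 and rises from 1551 to 2581. Scaffolds that fell and rose were 17 and 113 in the upper part of each list (10 and 73 with all peaks), and 2 to 12 and 38 to 94 with 1 list left out.

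Between testis and ovary, 3 windows fell and 1 rose in the upper part of each list, 1 and 1 with equal numbers, 7 and 5 with log2 reads, 1 rose with scaled lists, 0 fell and 1 rose with the gonad number as a replicate block (as a random block it gave 340 falls and 2352 rises between gonads and late lists, and 10 and 80 for scaffolds, so it moved no other count by over 1.5 times), and 0 to 1 either way with 1 list left out. From hours to late lists (1361 fell, 481 rose), 50 kb windows gave 897 and 249 and the upper part of each list 395 and 250; 271 fell with equal numbers and 1184 rose with scaled lists. With 1 list left out falls were 284 to 2113 and rises 117 to 764.

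The places of 0hr, 46hr and 60hr in gained windows were 42.0%, 66.6% and 88.5% of the way with 10 kb windows, 58.4%, 75.6% and 99.7% with 50 kb windows and 30.0%, 64.7% and 90.1% in the upper part of each list; there 0hr was at 30.0% in lost windows too. With lists scaled to the same covered length they were 27.3%, 48.2% and 65.0% in gained and 57.5%, 71.2% and 80.6% in lost windows. With 1 list left out, exact p ranged from 0.00216 to 0.0195 for covered length, 0.00649 to 0.0303 for width and 0.0179 to 0.0357 for the 3 shares by mark, and the within-class excess of overlap from 0.126 to 0.208. In the 3 shares by mark every gonad list lay above every late list. Their exact p was thus the smallest that the remaining splits can give, whichever list was left out.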

Other observations

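The window and scaffold tests by cover and the lists scaled to the same covered length were fixed before the data were examined; all other tests in this part were chosen after the data were seen. The peak with most reads was marked eliminated in 5 of 6 gonad lists and at 0hr and 46hr, and retained at 60hr and in the late lists. In testis2, ovary1 and ovary3 it lay at the same place on scaffold 35, near 1279879 to 1281364. At 0hr and 46hr it lay on scaffold 84, with 215930 and 158300 reads at 0hr and 351111 and 78972 at 46hr. In 7day and L1 it lay on scaffold 188, from 36316 to 43655 in 7day and from 39274 to 43223 in L1.

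Peaks marked eliminated were also found in the late lists, 102 at 5day, 33 at 7day and 38 in L1. Of these 173 peaks, 79 lay on scaffolds with both marks, and 10 of the 79 (12.7%, Wilson interval 7.02 to 21.8) lay within 20 kb of a border. Marks misplaced close to a border thus do not account for most of the 79. The other late peaks have no border on their scaffold. Borders were drawn from the marks themselves, so longer misplaced stretches were not tested. Scattered calls do not account for the eliminated peaks at 7day. Of these, 87.9% overlapped an L1 peak, against at most 27.3% over 100 random placements in the same blocks. In the other direction 57.9% of the L1 peaks overlapped one of 7day (at most 18.4% by placement). Of the 102 peaks at 5day, 21.6% overlapped one of 7day and 28.4% one of L1 (at most 8.82% and 9.80% by placement). Many 5day peaks thus recurred in neither list, and for those scattered calls remain possible. Of the 173 late peaks 81.5% overlapped a peak of any of the 6 gonad lists and 16.8% one of 46hr or 60hr, but the gonad lists hold more peaks; at 5day 68.6% overlapped testis1 (27.2% by placement) and 32.4% ovary3 (35.1%). Germ line cells that keep this DNA may be a source, and reads from repeated sequence with retained copies would give the same values, so the cause cannot be told apart here.

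More windows rose than fell from gonads to late lists. With lists scaled to the same covered length, 81.3% of calls still rose. This cannot show whether the longer covered length of the late lists accounts for the excess. Scaling leaves a window without a called peak empty, so peaks missed in a shorter list are not restored. Scaled lists have equal covered length, so an excess of calls that rose is then not an excess of cover. With log2 reads 43.3% of calls rose, so counting by covered length rather than by reads may account for the excess. No biological explanation of the excess was tested.

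For windows between gonads and late lists, 1 of the 84 splits of the 9 lists gave as many calls, the real one, with 2552 against at most 2 in any other. For scaffolds it was again 1 of 84, with 83 calls against at most 47. The split with 47 set testis3, ovary1 and ovary2 against the rest, and all 47 scaffolds were lower in these lists. They are the lists with the shortest cover (19.0, 28.8 and 21.7 Mb), so scaffold calls can follow list length. Chance can be excluded by shares of 1 in 84 only if the 6 gonad lists are independent, and same-numbered testis and ovary lists deviated together. The real split parts none of these pairs, and most of the 84 splits part at least 1. Of the 10 splits that part none, the highest other gave 0 windows and 0 scaffolds, and 10 are too few for a share under 0.05. For hours against late lists, 1 of 10 splits gave as many, the real one, with 1842 against 0 in the others, and for testis against ovary 10 of 10 did, with 0 calls in each; 10 splits are too few for a share under 0.05.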
